A study of Rattus norvegicus with 6 samples.

How the data were processed

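Genomic DNA of rat dorsal root ganglia was digested with MspI, ligated to methylated adaptors, bisulfite converted and sequenced as single-end reads of 50 bases, per the labels' protocols, from 1 µg of DNA with 100 pg of lambda phage DNA as an unmethylated spike. The rats were male Sprague-Dawley animals of 8 to 9 weeks and about 220 g, per the labels' protocols. The 6 libraries fall into SNL (n = 3) and Sham (n = 3), and the labels number them without saying which libraries came from separate animals. The p-values therefore measure the spread between these libraries, which may be technical in part. The labels describe the sham operation as done on the opposite side, so libraries of the 2 groups may share an animal.

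Reads were aligned with Bismark 0.18.1 and Bowtie2 and methylation was analysed with methylKit 1.3.3, per the submitters' processing notes. The labels' protocol text names a human assembly, while the submitters' processing notes name the rat assembly rn4, and the listed chromosome 1 positions reach up to 267910079. Coordinates are given as the files list them, as rn4. The per-library files hold, per the file headers, each CpG cytosine with its coverage as a read count and the percent of reads with C (methylated) or T (unmethylated). The deposited series table holds, for the 32674 nuclear sites used here, the percent methylation of each library, the authors' p-value and q-value, the authors' difference in percentage points, flags for promoter, exon, intron, CpG island and shore, and the distance to the nearest annotated transcript start. Every nuclear site with coverage of 100 reads or more in all 6 libraries is among the annotated sites, whose lowest coverage is 100. Mitochondrial sites were left out of all comparisons. The settings of the authors' test are not given in the sources used here. The authors' deposited p-values were matched to within 0.0018 on the log10 scale by a logistic likelihood-ratio statistic divided by a per-site overdispersion of at least 1 and referred to a chi-square distribution.

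Methylated read counts were recovered here as coverage times the percent of C. Strand is not recorded, and 2 neighbouring positions of 1 CpG are both listed for 1.4% of sites, which were kept as separate sites. A negative distance means upstream of the transcript start, which held for 8086 of 8123 transcripts within 2 bp. RefSeq identifiers were matched by accession to gene symbols in a RefSeq gene table of the assembly GRCr8, used for names only, and 7627 of 8123 transcripts (94% of sites) matched. A gene name means the nearest annotated start. The median distance to it was 45 kb and 23.2% of sites lay within 10 kb. The promoter, exon and intron flags can refer to another transcript. The promoter flag covers about 1 kb on each side of a start.

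Each site with coverage of 20 reads or more in all 6 libraries was tested with a logistic regression of methylated and unmethylated read counts on group. The overdispersion (Pearson chi-square over 4 residual degrees of freedom) was moderated across sites with limma's squeezeVar and kept at 1 or above, and a two-sided F test was adjusted by Benjamini-Hochberg at 0.05. The same test was run on the annotated sites alone, on counts summed over non-overlapping windows of 1000 bp with 3 or more sites, and on counts summed over the annotated sites of each gene (8016 genes). Sites within a read length can share reads, so such sums can count a read more than once. Differences are group means of the per-library percent, SNL minus Sham, in percentage points. In the report every adjusted p of a site, window or gene comes from this test. Mean methylation was compared with an exact permutation test over 20 arrangements, and feature classes with Fisher's exact test against all tested annotated sites. The 17 gene lists were tested with limma's camera (preset correlation 0.01) on logit values with a pseudocount of 1, and with fry. Software was R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

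The tests, gene lists and alternatives were fixed before the data were examined, except where an alternative is named as chosen afterwards. The sites named are the 12 largest increases and the 12 largest decreases among called annotated sites with no overlap between the groups, with 1 site per gene, the one with the lowest p. The windows named are the 5 largest in each direction, and for each list up to 3 genes with the lowest p were eligible. Values of some single genes are not reported here, while counts and group tests include them. Called sites of list genes, the called genes Prm3, Cplx2, Shh and Cables1 in the sums, and the 3 regions drawn were chosen after their values were seen.

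The test was tested on simulated data drawn from the real coverage and levels, with 100 sites changed by 10 points and 100 by 20 points. Among the annotated sites it recovered 27% of the former and 82% of the latter, 109 in all, with 18 false calls. All 18 lay at the 321 sites simulated with high overdispersion. Over all 210270 sites it recovered 3% and 39% with 179 false calls beside 42 recovered changes, 162 of them at 866 sites simulated with the high overdispersion seen there. For windows it recovered 23% and 71% with 15 false calls, and for genes 59% and 82% with 12. On the same simulated sites and windows, limma on logit values and an F test with unmoderated overdispersion recovered 0%. On simulated genes limma recovered 43% and 70% with 9 false calls, and the F test 6% and 31% with 0. Limma's camera called a simulated list of 50 genes all lowered by 8 points and did not call an unchanged list. The genes were simulated as independent and the change exceeds every list median seen here. It therefore does not show whether camera could find shifts of the size of those medians.

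Summed coverage was 27247702 to 34293779 reads per library, with 1741191 to 1916639 listed sites and a median of 4 to 5 reads, so most listed sites were left out by the coverage minimum. PCR copies cannot be told apart without molecular identifiers, so coverage can overstate the number of DNA molecules. Alternatives covered a replicate block, no overdispersion, unmoderated overdispersion, limma, other coverage minimums (10, 50 and 100), a minimum difference of 10 or 25 points, removal of sites over the 99.9th percentile of coverage or with a within-group range over 30 points, summed strands, other windows, and leaving out each library in turn. A robust prior, a prior trended on coverage, library offsets, an overdispersed chi-square test and genes restricted to sites within 10 kb of the start were added after seeing the data. The lambda spike was not analysed here.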

Results

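DNA methylation was measured in dorsal root ganglia (DRG), which hold the cell bodies of the sensory neurons that run in the spinal nerves, of adult male Sprague-Dawley rats. In spinal nerve ligation (SNL), a surgical model of neuropathic pain, the left L5 and L6 spinal nerves are tied off. The comparison asks where CpG methylation in the ganglion differs from the level after a sham operation. Per the labels, the sham operation, without a ligature, was done on the opposite side. There were 3 SNL and 3 Sham libraries, all taken 3 weeks after surgery. Reduced representation bisulfite sequencing (RRBS) reads CpG-rich restriction fragments, so each value is the share of reads that kept a cytosine at a CpG. The summed coverage over listed CpG cytosines was 31651277, 34293779 and 29420922 reads for SNL 1 to 3 and 32243538, 31063811 and 27247702 reads for Sham 1 to 3. Coverage reached 20 reads in all 6 libraries at 210270 nuclear sites, where the median was 49 reads, and 100 reads at 32674 nuclear sites, where it was 214 reads. For the latter the authors deposited gene and CpG island annotation. The median SD between libraries of a group was 3.4 percentage points per site over the former and 1.9 points over the latter.

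The DRG methylome as a whole differed little between the groups. Mean methylation over the 210270 sites was 66.44% ± 0.75 (SD, n = 3) after SNL and 67.36% ± 0.36 (SD, n = 3) after sham surgery, a difference of -0.92 points (exact two-sided permutation p = 0.2). In sites with mean methylation over 80% the difference was -0.85 points, and on chromosome X it was -1.31 points, each with all 3 SNL libraries below all 3 Sham libraries (exact permutation p = 0.1 for both). Intergenic sites averaged 70.58% ± 0.84 and 71.69% ± 0.44 (SD, n = 3), whereas promoters averaged 15.42% ± 0.17 and 15.61% ± 0.15 and CpG islands 10.07% ± 0.18 and 9.88% ± 0.1, in SNL and Sham respectively. The adjusted p over the 14 classes was 0.28 or more, and 3 libraries against 3 cannot give an exact p under 0.1.

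Against this background, single CpG sites lost methylation after SNL. Of the 32674 annotated sites, 464 differed at an adjusted p under 0.05, 405 of them lower and 59 higher after SNL (87.3% lower), and 226 differed by at least 10 points. The deepest loss lay 18.7 kb upstream of Rpl21, which encodes a protein of the large ribosomal subunit (chromosome 12, position 8738457, rn4). Its methylation was 39.6% ± 5.8 after SNL and 79.5% ± 1.2 in Sham (SD, n = 3), a difference of -39.9 points ± 3.4 (SE, adjusted p = 3.85e-08, 648 to 888 reads per library). An intronic site whose nearest start is that of Scarna3, a small Cajal body RNA, stood at 46.1% ± 11.3 against 83.2% ± 3.6 (105 to 191 reads). An intronic site 20.1 kb from the start of Oxa1l, which inserts proteins into the mitochondrial inner membrane, stood at 41.9% ± 1.5 against 74.4% ± 5.1 (100 to 209 reads). In an intron of the region assigned to Insr, the insulin receptor, methylation was 13.5% ± 6.7 against 43.5% ± 9.1 (134 to 262 reads).

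The other named losses were assigned to genes of varied function. Cplx2, whose product complexin regulates synaptic vesicle fusion, had a site 41 kb upstream of its start at 37.9% ± 2.7 after SNL and 65.2% ± 3.8 in Sham (SD, n = 3; adjusted p = 7.4e-07, 626 to 893 reads). Prkacb, a catalytic subunit of protein kinase A, had a site 79 kb upstream at 39.3% ± 2.1 against 64.5% ± 3.2 (adjusted p = 0.00353). Diaph3, a formin that builds actin filaments, had a site 15.2 kb downstream of the named start at 50% ± 0.7 against 77.9% ± 2 (adjusted p = 9.44e-08). The site assigned to Rraga, a Rag GTPase of mTORC1 signalling, was 607.2 kb from that start and fell by 27.8 points (adjusted p = 1e-06). The remaining named losses were Prm3 (-29.8 points), Clic6 (-28.1), Siah3 (-25.8) and Specc1 (-25.4), with adjusted p from 2.3e-05 to 0.00231. All 12 named losses had the 3 SNL libraries below the 3 Sham libraries and kept their call without any of the 6 libraries in turn.

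Gains were fewer. The median difference of the 59 called gains was 10.7 points and that of the 405 called losses -9.6 points. The largest gain lay 49.2 kb upstream of Kank1, an organiser of the cortical cytoskeleton, at 62.5% ± 4.6 after SNL and 38.4% ± 6.2 in Sham (SD, n = 3; chromosome 1, position 228698920, adjusted p = 0.00816, 109 to 203 reads). An intronic site of the region assigned to Cmip stood at 67.9% ± 0.9 against 46.7% ± 7.2 (adjusted p = 0.00123). Tfap2a, a transcription factor of the neural crest from which DRG neurons and glia derive, gained 15.4 points ± 1.9 (SE) at a site 5.7 kb upstream (50.8% ± 2.6 against 35.4% ± 1.9, adjusted p = 0.00522). The site of Shh, the secreted Sonic hedgehog ligand, rose to 24.7% ± 0.9 from 11% ± 1. These 4 kept their call without any library in turn. The other 8 named gains did not. Of the named gains 4 lost the call without SNL 1, 7 without SNL 2, 5 without SNL 3, 7 without Sham 1, 2 without Sham 2 and 8 without Sham 3. The 8 differed by 13.4 to 17.1 points. They were Prpf18 (a splicing factor), Mboat2, Ndrg2, Tmem260, Ppm1l (a protein phosphatase), Shc4 and the transcripts NM_001106032 and NM_001107033.

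**Figure D1:**
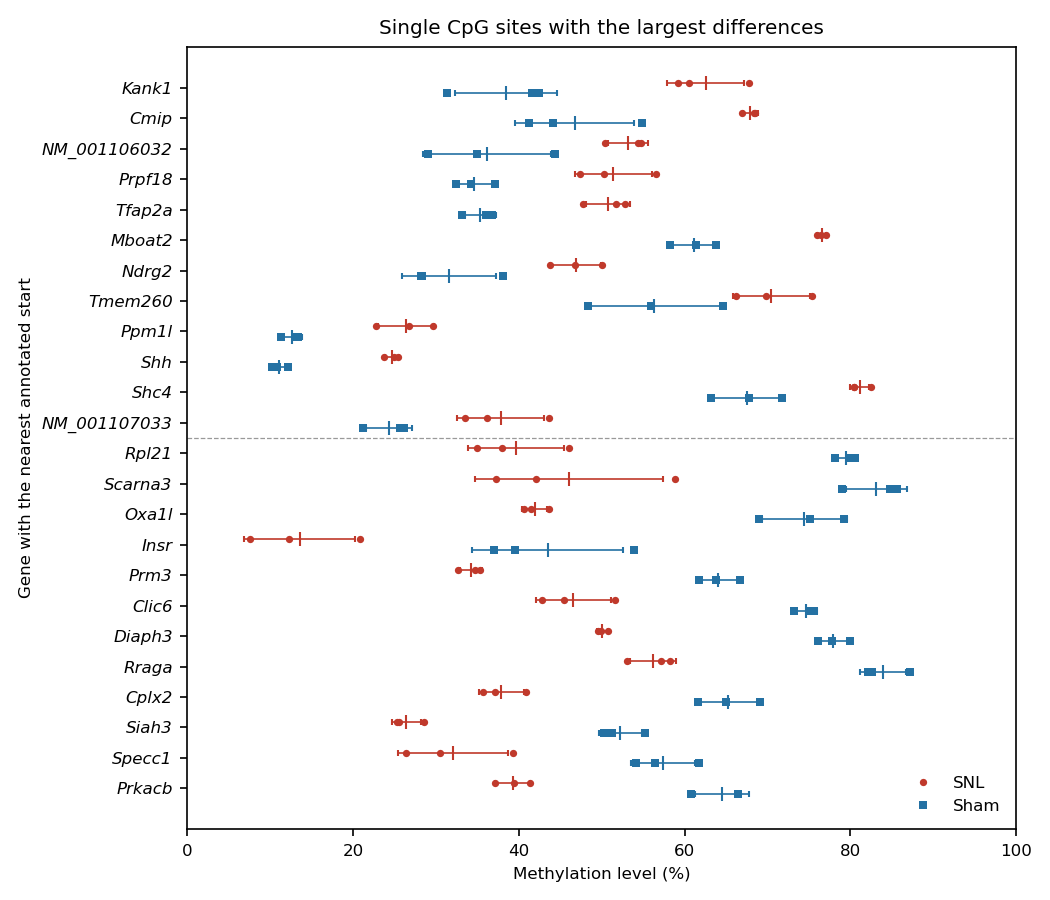
Methylation level in percent (horizontal axis) of the 24 named CpG sites, labelled by the gene with the nearest annotated start (vertical axis), with a point per library, a tick at the group mean and a bar of 1 SD (n = 3). SNL libraries lie to the right of all Sham libraries for the 12 sites above the dashed line and to the left for the 12 below it, where Rpl21 shows the widest gap (39.6% against 79.5%).

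Of the 464 called annotated sites, 114 kept their call without any library in turn (102 lower, 12 higher). The count of calls was 522 without SNL 1, 236 without SNL 2, 305 without SNL 3, 292 without Sham 1, 251 without Sham 2 and 129 without Sham 3. When each library was given its own offset, which removes a shift common to all sites, 421 sites were called and 253 were lower (60.1%). The direction split thus depended on this scaling, while all 24 named sites kept their call. Without moderation of the spread across sites, an F test called 0 annotated sites (1968 at an unadjusted p under 0.05) and limma on logit values called 0 (3480). The moderated test had 4290 at that level, where a share of 0.05 of the tested sites is expected by chance. On simulated changes at these sites both other tests recovered 0%. In 463 of the 464 called sites the groups did not overlap, which the test itself selects for. Over all tested annotated sites the share was 17.8%, against 10% expected by chance for 3 against 3.

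**Figure D2:**
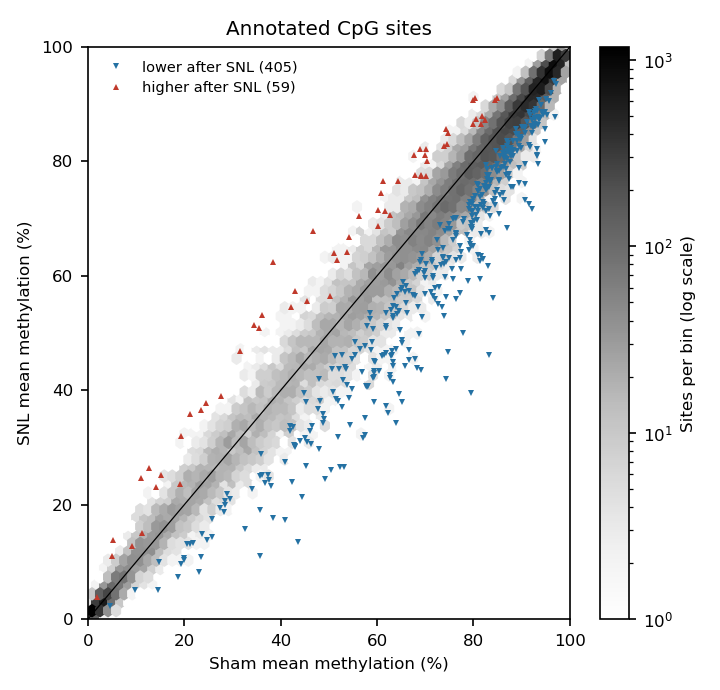
Mean methylation in percent of the 32674 annotated sites in Sham (horizontal axis) and SNL (vertical axis), with grey bins shaded by the number of sites on a log scale and the line of equality. The 405 sites called lower (blue) and 59 called higher (red) lie mostly at intermediate methylation.

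Neighbouring CpGs changed together at several places. At Prm3, a gene of the protamine cluster known from sperm cells, the authors' flags place 4 listed CpGs in its promoter and exon, and all 4 were lower after SNL (chromosome 10, positions 4814927, 4814939, 4814950 and 4814958). Their means were 31.7% ± 2.2, 34.2% ± 1.4, 36% ± 3.1 and 26.5% ± 2.1 after SNL, against 57.1% ± 3.4, 64.1% ± 2.5, 62.2% ± 0.8 and 53.1% ± 4 in Sham (SD, n = 3; at least 205 reads per library). Upstream of Cplx2, positions 16363892 and 16363918 on chromosome 17 were both lower (35.3% ± 1.6 against 57.4% ± 2.6 for the latter). The 4 other listed positions within 600 bp, 2 of them neighbours in 1 CpG, did not pass (adjusted p from 0.76 to 0.919). Their lowest coverage was 111, 37, 20 and 21 reads, against 626 and 630 at the called positions, so a change there could be missed. In a CpG island in an exon of Shh, positions 2209638, 2209646 and 2209650 on chromosome 4 rose from 4.9% ± 0.5, 11% ± 1 and 5.1% ± 0.8 to 11.1% ± 1.2, 24.7% ± 0.9 and 13.8% ± 2, at 769 reads or more. A CpG at position 2209754, with as few as 57 reads, stood at 34.6% ± 9 against 28.5% ± 7.7 and did not pass (adjusted p = 0.83).

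**Figure D3:**
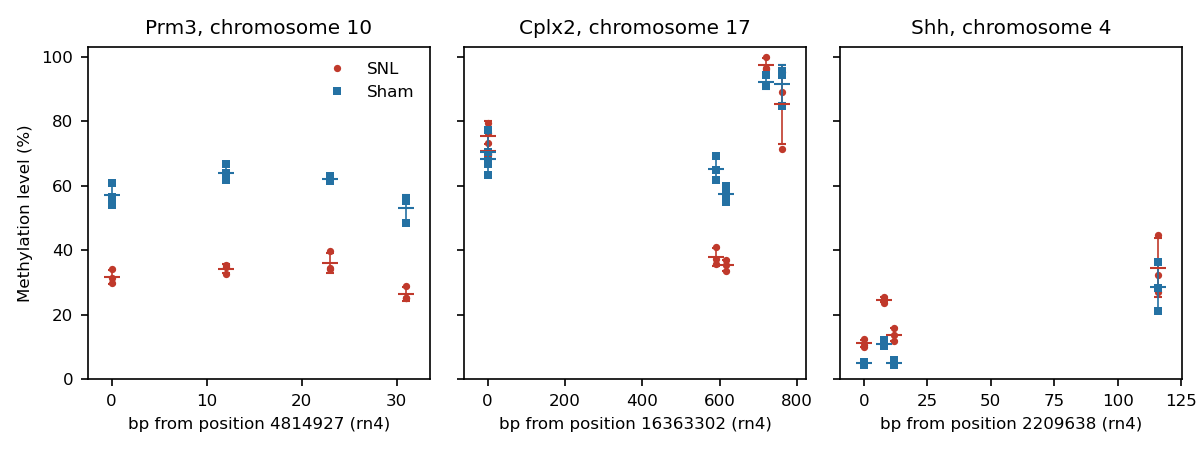
Methylation level in percent (vertical axis) of each listed CpG at the Prm3 promoter, upstream of Cplx2 and in the Shh exon, against its distance in bp along the chromosome (rn4), with a point per library, the group mean and a bar of 1 SD (n = 3). The 4 Prm3 sites are all lower after SNL, 2 of the Cplx2 sites are lower, and 3 Shh sites are higher.

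Called sites were found mainly at intermediate methylation. Sites with mean methylation of 20 to 80% made up 68.4% of the lower and 69.5% of the higher calls but 30.9% of all tested annotated sites (Fisher's exact test, odds ratio 4.95, adjusted p = 1.94e-53 for the lower calls, and 5.11, adjusted p = 7.73e-09 for the higher). Lower calls lay outside CpG islands and shores in 92.3% of cases against 85.5% of tested sites (odds ratio 2.05, adjusted p = 0.000112). They were scarce in CpG islands (4 of 405, odds ratio 0.21, adjusted p = 0.000261) and in exons (4 of 405, odds ratio 0.25, adjusted p = 0.00342), and promoters held 20 of the 405 (odds ratio 0.66, adjusted p = 0.101). Of the 59 higher calls, 24 lay in introns (odds ratio 2.09, adjusted p = 0.0141) and 0 in promoters (odds ratio 0, adjusted p = 0.0424). With 1 site per 1-kb window, the intermediate class held for both directions and the excess outside islands held for the lower calls (odds ratios 3.8, 7.24 and 1.97), while the island, exon, intron and promoter calls did not pass. Neighbouring sites are not independent, and a site at 20 to 80% can move further in points than a site near 0% or 100%. The class mean was taken over all 6 libraries, SNL included, so a large change can itself place a site in this class. The Scarna3 site, at 83.2% in Sham and 46.1% after SNL, is an example. The excess at intermediate methylation can therefore come in part from the changes themselves.

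Over all 210270 sites with 20 reads or more, 1179 were called, 977 lower and 202 higher (82.9% lower), and 704 differed by at least 10 points. On simulated data of this depth 179 false calls stood beside 42 recovered changes, so these calls are less certain than those at annotated sites. There 18 false calls stood beside 109 recovered changes, also above a share of 0.05. The unmoderated F test and limma called 0 (5131 and 14361 at an unadjusted p under 0.05). By chance a share of 0.05 of the 210270 sites is expected at that level, and the F test count lies below it. With library offsets the split was 573 lower and 389 higher (59.6% lower). In 44 of the 1179 the values within a group spanned over 30 points, a spread that a DNA variant between rats can give. Summed over 1-kb windows, 220 of 29759 windows were called, 186 lower and 34 higher (84.5% lower, 61.8% with library offsets). The F test and limma called 0 windows (1524 and 2602 unadjusted). The F test count is close to the share of 0.05 expected by chance. The largest losses were the windows at chromosome 16, 83729000 to 83729999 (35.1% ± 11 against 75% ± 4.8) and chromosome 12, 8738000 to 8738999, which holds the Rpl21 site (40.4% ± 6.2 against 79.6% ± 1). Further losses lay at chromosome 11, 66989000 to 66989999 (31.4% ± 2.6 against 69.1% ± 4.8), chromosome 12, 22293000 to 22293999 (18.7% ± 4.3 against 55.3% ± 6.1) and chromosome 2, 242851000 to 242851999 (35.1% ± 7.7 against 67.8% ± 7.1; SD, n = 3). The largest gains lay at chromosome 14, 101130000 to 101130999 (66.1% ± 3.5 against 44.7% ± 8.8) and chromosome 5, 135262000 to 135262999 (48.9% ± 2.2 against 28.5% ± 4.3). On chromosome 2 gains lay at 182483000 to 182483999 (24.7% ± 2.7 against 8.7% ± 3.9), 79683000 to 79683999 (65.2% ± 2.3 against 49.3% ± 0.4) and 51744000 to 51744999 (74% ± 4.3 against 58.4% ± 4.9). Apart from the Rpl21 window, these hold no site of the annotated table, so no gene is assigned. Without SNL 1, SNL 2, SNL 3, Sham 1, Sham 2 and Sham 3 in turn, 688, 589, 530, 752, 700 and 369 sites and 254, 130, 137, 117, 147 and 94 windows were called. In the same order 3, 3, 2, 2, 2 and 3 of the 10 named windows lost their call.

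When counts were summed over all annotated sites of a gene, 43 of 8016 genes were called, 41 lower and 2 higher, and with library offsets 34 were lower and 10 higher. Close sites can share reads, as the 4 sites of Prm3 can, so summed counts are not all independent. Limma called 6 genes and the unmoderated F test 0. The moderated test, limma and the F test had 1095, 1036 and 695 genes at an unadjusted p under 0.05. On simulated genes limma recovered 43% and 70% of changes of 10 and 20 points, against 59% and 82% for the moderated test. Most of the 43 calls thus depended on the choice of test. Prm3 fell from 59.1% ± 1.5 to 32.1% ± 0.8 and Cplx2 from 63.4% ± 1.9 to 43.5% ± 1.2 (SD, n = 3; adjusted p = 0.000503 and 0.000863). The genes that rose were Shh (22.6% ± 0.8 to 29.5% ± 0.5, adjusted p = 0.011) and Cables1, a regulator of cyclin-dependent kinases (69% ± 3.5 to 82.2% ± 1, adjusted p = 0.0351). Cables1 had 1 annotated site, so its sum is that site. The number of called genes was 3 without SNL 2 or SNL 3, 5 without Sham 2 or Sham 3, 31 without Sham 1 and 74 without SNL 1. Prm3, Cplx2 and Rpl21 kept their call without any library in turn. Rpl21 also had 1 annotated site, the one named above, so its sum adds nothing to that site. The call of Shh was lost without SNL 2, SNL 3 or Sham 3 (adjusted p = 0.0785, 0.0686 and 0.115), and that of Cables1 was lost without each of the 6 libraries.

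Gene groups linked to pain and neuronal excitability were compared by their called sites, against 464 of all 32674 annotated sites (1.42%), without a test of the rates. Of the sites of sodium, calcium, HCN and TRP channel genes 2 of 121 were called, and of those of neurotransmitter receptor genes 2 of 126. None of the 135 sites of the 23 measured potassium channel genes was called, and none of the 23 genes passed (0 also when adjusted over the list alone). Kcnq5, a subunit of the M-type potassium channel, stood at 88.2% ± 1.1 after SNL against 91% ± 0.4 and Kcnq3 at 60% ± 2.2 against 67% ± 2.2 (SD, n = 3; adjusted p = 0.13 and 0.212). Of 27 sodium, calcium, HCN and TRP channel genes none passed over all genes and 2 were lower when adjusted over the list alone. These were Asic1, an acid-sensing channel (65.5% ± 3 against 77.1% ± 1.6, adjusted p = 0.0926 over all genes), and Cacna2d1, the calcium channel subunit that binds gabapentin (78.7% ± 2.3 against 83.4% ± 0.8, adjusted p = 0.136). Each held 1 called lower site, an Asic1 intron site at -14.2 points and a Cacna2d1 site 154 kb upstream at -5.7 points. Neither site kept its call with library offsets. Of 37 neurotransmitter receptor genes none passed over all genes and 1 was lower adjusted over the list alone, the kainate receptor gene Grik2 (80.6% ± 0.5 against 84.9% ± 1.7). Called lower sites lay in the regions assigned to Grik2 and to the glutamate receptor gene Grm7, at 775.2 and 886 kb from their starts.

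The 24 injury and regeneration genes had none that passed (0 adjusted over the list alone) and 1 called site, the Cacna2d1 site, which this list shares. Among 25 genes of sensory neuron identity none passed (0 adjusted over the list alone), and 4 sites were called. Those of the GDNF co-receptor gene Gfra1 (-9.5 points) and the neurofilament gene Nefl (-6.9) were lower, and those of the transcription factor gene Runx1 (11.5) and of Ntrk2, the receptor of BDNF (5), were higher. The Gfra1 site kept its call in 5 of the 6 fits without a library, the Nefl and Ntrk2 sites in 1 and the Runx1 site in 0.

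Glial and other cell type lists were measured in the same way. Of 16 Schwann cell and myelin genes Shh was higher over all genes, a call lost without SNL 2, SNL 3 or Sham 3. In this list 2 were higher and 3 lower adjusted over the list alone, among them Ncam1 (28.7% ± 2.1 against 23.7% ± 0.1) and Egr2, the myelination transcription factor (53.2% ± 0.9 against 64% ± 1.6; SD, n = 3). Shh, Ncam1 and Egr2 passed over the list alone without any library in turn. None of the 13 satellite glia genes passed (0 adjusted over the list alone), and called sites in the regions assigned to Sox2 (-14.1 points) and Sox9 (-3.4) were lower. None of 19 fibroblast and matrix genes passed over all genes and 1 was lower adjusted over the list alone, Tgfb1 (8.6% ± 1.7 against 14.2% ± 1.5). An intronic site of Tgfb1, in a CpG shore, was lower by -16.6 points, and a site 490.9 kb upstream of Tgfbr2, a receptor of that cytokine, by -21.3 points (61.8% ± 1.9 against 83.1% ± 1, adjusted p = 6.93e-05). Macrophage and microglia genes (17 measured), lymphocyte genes (11), endothelial and mural genes (10) and muscle and adipose genes (8) had none that passed, over all genes or adjusted over the list alone. The Runx1 site, shared with the neuronal list, was the only called site among them.

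Of 17 genes of DNA and histone methylation none passed over all genes and 2 were lower adjusted over the list alone, Dnmt3l, a cofactor of the de novo methyltransferases (76.1% ± 1.6 against 80.1% ± 0.9) and Mbd2, a reader of methylated DNA (46.7% ± 1.4 against 50.2% ± 0.5; SD, n = 3). A site 212.9 kb downstream of the start of Gadd45g, a stress gene linked to DNA demethylation, was lower by -16.3 points. Of 38 axon guidance and synaptic adhesion genes 1 was lower over all genes and 3 were lower adjusted over the list alone, among them Sema7a (45.1% ± 4.4 against 59.4% ± 3.4) and Unc5d (79.4% ± 1.1 against 82.4% ± 0.2). All 5 called sites of this list were lower, among them 2 assigned to Dcc and 1 each to Sema7a and Ephb1. Sema7a had 1 annotated site, so its gene value and its called site are the same measurement. Of 39 Wnt, BMP, Hedgehog and Notch genes 1 was higher, Shh, over all genes and adjusted over the list alone. Its call over all genes was lost without SNL 2, SNL 3 or Sham 3, and that over the list alone was kept without any library in turn. Of 13 imprinted genes none passed over all genes and Ascl2, with 1 annotated site, was lower adjusted over the list alone (48.4% ± 1.8 against 59% ± 2.5). Of 18 Hox genes none passed with either adjustment.

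Tested as groups against the other genes, 0 of the 17 lists stood apart (limma's camera, lowest adjusted p = 0.385, for the Wnt, BMP, Hedgehog and Notch list, and 0 with an estimated correlation, lowest adjusted p = 0.989). At an unadjusted p under 0.05 camera gave 1 list, and the rotation test fry gave 0 lists adjusted and 2 unadjusted for movement in 1 direction. For change in either direction fry gave 8 lists, with the lowest adjusted p for axon guidance and synaptic adhesion (6.02e-05) and Schwann cell and myelin genes (0.000117), a test that does not compare a list with other genes. All 17 list medians were below 0, from -2.11 points for imprinted genes to -0.03 for the methylation machinery, and the median over all genes was -0.79. For the satellite glia list the median was -0.54 and the mean 1.23 points, for endothelial genes -0.75 and 0.08, and for the Wnt list -0.26 and 0.2, so median and mean differed in sign there. Camera pointed up, against a negative median, for these 3 lists and for the macrophage, fibroblast and methylation machinery lists. Of the called sites of list genes, the 3 Shh sites and the Tgfbr2 site kept their call without any of the 6 libraries. The sites of Asic1, Cacna2d1, Nefl, Sox9, Dnmt3l, Ascl2, Dcc and Ephb1 lost it with library offsets. Of the genes that passed only over their list alone, Dnmt3l and Mbd2 passed in 3 of the 6 fits without a library (not without SNL 2, SNL 3 or Sham 3), as did Sema7a (not without SNL 3, Sham 2 or Sham 3). Grik2 and Tgfb1 passed in 2 (without SNL 1 or Sham 1), Asic1 and Unc5d in 2 (without SNL 1 or SNL 3), Cacna2d1 in 1 (without SNL 1) and Ascl2 in 1 (without Sham 2).

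The authors' deposited table gives its own p-values, q-values and differences for the same 32674 sites. In the authors' deposited table, a total of 1484 sites had a q-value under 0.05, 1253 lower and 231 higher after SNL, and 16 of them differed by 25 points or more. Of the 464 sites called here 450 had a q-value under 0.05 in the authors' deposited table, and all 464 had the same sign there.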

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

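The tests of mitochondrial DNA, library offsets and cell makeup, and the split counts over sites, were chosen after the result was seen, while the test of median coverage ratios and the split counts over windows, genes and lists were written before. The spread of the coverage ratios was looked at afterwards.

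Mitochondrial CpGs, which no comparison used, were read as methylated slightly more often after SNL, a difference between the groups in data outside the main measurement. Over 14 sites with 100 reads or more in every library, the methylated share was 1.81%, 1.82% and 1.92% in SNL 1 to 3 (95% exact binomial intervals 1.72 to 1.9, 1.72 to 1.93 and 1.83 to 2.02) and 1.77%, 1.7% and 1.75% in Sham 1 to 3 (1.71 to 1.83, 1.62 to 1.77 and 1.68 to 1.83). The difference was 0.11 points (exact permutation p = 0.1, the smallest that 3 against 3 can give), and intervals cover counting error only. These sites also held fewer reads in SNL (80833, 66629 and 77669) than in Sham libraries (173140, 106701 and 114335), and whether this bears on the share was not tested.

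The predominance of losses (405 of 464 called annotated sites) was weighed against technical and cellular explanations. A shift over all sites of a library stays open. With library offsets and 1 site per 1-kb window 61.9% of calls were lower (95% exact interval from 56.6%), against 87.1% without offsets. Much of the imbalance thus moved with the offsets. These were medians over sites at 20 to 80%, where most calls lay, and can also remove a difference confined to that class. The mean difference was -1.65 points at 20 to 80%, -0.85 over 80% and 0.14 under 20%. The interval treats sites as independent although all come from the same 6 libraries, and the offset is 1 value per library. The remaining excess therefore cannot decide whether such shifts are the whole cause. Incomplete bisulfite conversion would raise apparent methylation, and the mitochondrial share was higher, not lower, after SNL by 0.11 points. Amplification that favours 1 allele stays open, since it can raise or lower depth: the median log2 coverage ratio of lower sites exceeded that of uncalled sites at 20 to 80% by 0.053 (bootstrap interval 0.039 to 0.068), but 64.4% of the lower sites lay above and 35.6% below that reference, so the limit of 0.1 on the median set beforehand could not decide it, and called lower sites were also deeper (median 480 against 213 reads). A change in the cell makeup of the ganglion may contribute and stays open, as does an effect of the ligation itself. Had resident cells kept their proportions and levels, newly present cells would have to give at least 50.2% of the DNA at the Rpl21 site. That site had the largest fall, and at the Insr site the bound was 69%. A shift in proportions among resident cells needs no new cells and is not covered by this bound. No cell type list stood apart (lowest adjusted camera p 0.549). A bound of this kind cannot exceed 100%, so it could not have excluded the explanation.

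With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in every case but the gene lists the real split gave the highest count (1 of 10). The real split and the highest other split gave 1179 and 629 calls for all sites, 464 and 57 for annotated sites, 220 and 60 for windows, and 43 and 2 for genes. The highest other split was that of SNL 1, SNL 3 and Sham 1 against the rest in all 4 of these. This split keeps SNL 3 with Sham 1 and SNL 2 with Sham 2, the pairs that match at polymorphism-like sites, and so does that of SNL 1, SNL 2 and Sham 2, with 359 calls for all sites and 10 for annotated sites. Neither the splits nor any fit took both pairs into account. The only block used was the replicate number, which joins SNL 2 with Sham 2 but not SNL 3 with Sham 1. For the gene lists all 10 splits gave 0.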

How the results depend on the processing

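The library offset, robust and trended priors, overdispersed chi-square test and 10-kb limit were chosen after seeing the data, and where no reason is given the cause was not tested. Counts are for all sites, annotated sites, windows and genes in this order (1179, 464, 220 and 43), and lower calls outnumbered higher ones in every setting with calls. Without overdispersion they were 4200, 3315, 3132 and 1969. Unmoderated overdispersion gave 0, 0, 0 and 0 (5131, 1968, 1524 and 695 at an unadjusted p under 0.05). By chance a share of 0.05 is expected at that level, and the 5131 of all sites lie below it. Limma gave 0, 0, 0 and 6 (14361, 3480, 2602 and 1036 unadjusted). Both tests also recovered 0% of simulated changes of 10 and 20 points at sites and windows. At simulated genes, however, limma recovered 43% and 70% of changes of 10 and 20 points, against 59% and 82% for the main test. With the overdispersed chi-square test annotated sites, windows and genes gave 1411, 1058 and 634, and with the robust prior annotated sites gave 797. A minimum of 10 points left 704, 226 and 128, and of 25 points 194, 16 and 19. Coverage minimums of 50 and 100 gave 713 and 464 sites and 68 and 31 windows, with fewer sites tested, and a minimum of 10 gave 382 windows. Windows numbered 400 without polymorphism-like sites and 710 with 1 or more sites each. Leaving out each library gave 369 to 752, 129 to 522, 94 to 254 and 3 to 74 calls.

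The replicate numbers did not pair the libraries throughout. The deviations of same-numbered libraries from their group means correlated at -0.05, 0.26 and -0.14 for numbers 1 to 3. Among the Sham libraries SNL 2 correlated best with Sham 2, its own number, whereas SNL 3 did with Sham 1 (0.34). With the replicate number as a block the counts were 0 (3437 at an unadjusted p under 0.05), 104, 116 and 10, and 0 lists. The 3437 lie below the share of 0.05 of all sites that is expected by chance.

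The mean difference of -0.92 points lay between -1.34 and -0.62 without each library in turn, and that of exons (-0.1) turned to 0.05, 0.11 and 0.04 without SNL 2, SNL 3 and Sham 3 (range -0.46 to 0.11). Among the odds ratios, that of promoters for higher calls was 0 with 1 site per 1-kb window and 0 with at least 10 points, no longer past the threshold. In the same order, lower calls in exons (0.35, 0.27), islands (0.17, 0.33) and shores (0.6, 0.82) did not pass. Higher calls in introns did not pass with 1 site per window (2.08), nor lower calls outside islands and shores with at least 10 points (1.54). With at least 10 points lower calls in introns passed (1.75), the ratio for intergenic lower calls turned from 1.12 to 0.7, and that for higher calls in islands from 1.54 to 0.64. All 24 named sites kept their call with library offsets and 13 kept it under the block.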

Other observations

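The test of polymorphism-like values in pairs of libraries and the test of within-group ranges were chosen after the result was seen, and the held-out tests were written before.

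Further genes with a change in their summed counts are given as single values, picked after their values were seen and with no test of a shared function. Tenm3, a teneurin of synaptic partner matching, stood at 74.2% ± 0.9 after SNL against 78.2% ± 0.9 over 30 sites, Cdh10, a cadherin, at 80.4% ± 0.3 against 85.1% ± 1.3 over 16 sites, and Disc1, a scaffold protein of neuronal development, at 87.6% ± 0.6 against 91.3% ± 0.2 over 11 sites (SD, n = 3; limma-moderated adjusted p = 0.0351 for each). Also lower were Ccnd1, cyclin D1, at 37.6% ± 0.6 against 44.9% ± 1.4 (adjusted p = 0.0492), Ezr, the membrane linker ezrin, at 49.8% ± 2.9 against 68.7% ± 1.1, Plec, plectin, at 67.6% ± 2.7 against 77.7% ± 1.1, and Hmga1, a chromatin protein, at 55.7% ± 2.8 against 68.8% ± 3.3 (adjusted p = 0.011, 0.0351 and 0.0458). The Ezr value rests on 1 site. Aftph fell from 48.7% ± 4.4 to 27.5% ± 2.5 over 3 sites (adjusted p = 0.011). None of these 8 genes kept its call without every library in turn: Aftph lost it without SNL 2 or SNL 3, Tenm3, Cdh10 and Ezr without SNL 2, SNL 3, Sham 2 or Sham 3, and Disc1 and Plec without any library but SNL 1. Ccnd1 and Hmga1 lost it without each of the 6.

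Some genes were assigned several called sites. Where these lie within a read length they can share reads and are not independent. Ikbkb, a kinase of NF-kappaB activation, and Synm, the intermediate filament protein synemin, each had 4 called sites, all lower. Only 1 of the Ikbkb sites and 2 of the Synm sites kept their call without every library in turn, whereas the 4 Prm3 sites did. The other 3 Ikbkb sites were called only with SNL 1 left out, among those 6 fits. Cd9, a tetraspanin, had 3 lower sites, all lost without SNL 3, Sham 2 or Sham 3. In all, the 464 called sites were assigned to 372 genes, 72 of them with more than 1 called site.

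At 617 sites where the 6 libraries span over 50 points, as genotype differences between rats can make them do, SNL 3 matched Sham 1 (Pearson r across sites 0.87) and SNL 2 matched Sham 2 (0.85), and the highest of the other 13 pairs was 0.58, Sham 2 with Sham 3. Sites are not independent replicates. A candidate explanation is that each of these pairs came from the 2 sides of 1 rat (lowest r of the pairs 0.85), which the described sham side allows, although SNL 1 and Sham 3 had no such partner. Reads passed between the libraries of a pair would shrink their difference and stay open: at lower sites called from the other 4 libraries the median difference of the held-out SNL 3 and Sham 1 was 1.15 times that of SNL 1 and Sham 3 (bootstrap interval 0.99 to 1.43), but over the 7 unmatched pairs as reference the ratio ran from 0.54 to 2.09, and from 0.68 to 2.63 for SNL 2 and Sham 2, so the bound of 0.75 set beforehand for a single reference was too lenient. Labels swapped within a pair would turn directions, but at least 98.4% of sites called from the other 4 libraries kept their direction in these pairs. Over all 9 SNL and Sham pairs the share ranged from 67.8% (SNL 2 and Sham 1) to 100% (SNL 2 and Sham 2). Of the higher calls alone, 17 of 61 kept it for SNL 2 and Sham 1 and 43 of 110 for SNL 3 and Sham 2. Of the lower calls in these pairs 175 of 222 and 133 of 147 did.

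Sequence differences between rats could also pass as methylation changes. Of the 464 called annotated sites 0% had a within-group range over 30 points, and of the 1179 calls over all sites 3.7% (44) did. This excludes nothing, since only 95 of the 32674 tested annotated sites had such a range, the call selects against it, and a variant that separates the groups gives none. The matched pairs were SNL 3 with Sham 1 and SNL 2 with Sham 2. If each came from 1 rat, an inherited variant would give both members the same value. At annotated sites called lower from the other 4 libraries, these held-out pairs still differed by medians of -9 and -11.3 points. However, the 4 libraries that made these calls held the other matched pair. On that condition variants were selected against before the held-out pair was read. The medians therefore cannot decide how many of the calls are variants. The condition itself is not settled and no genotypes were used, so single sites stay undecided in either set.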
